A study of Rattus norvegicus with 202 samples.

How the data were processed

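DNA methylation at CCCGGG sites was measured by digital restriction enzyme analysis of methylation in 202 libraries of rat dorsal root ganglion, spinal cord, prefrontal cortex, spleen and liver. The authors named Bowtie2 and SAMtools, without versions, and genome build rn4. The deposited tables list 151928 sites per library with counts of methylated, unmethylated and total reads, the raw methylation in percent and an adjusted methylation in percent. Checked on the tables, the deposited raw percent is the methylated share of the reads of a site, and the authors' adjusted percent multiplies the odds of methylation by 1 factor per library, from 0.414 to 2.647. What this factor was calibrated on is not stated, so the counts as deposited were used and the adjustment was an alternative.

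Total reads per library ranged from 883254 to 118920131. The median number of reads at sites with at least 20 reads ranged from 49 to 647 between libraries. Reads carry no molecular identifiers, so depth covers counting error only. A site was tested when it had at least 20 reads in at least 75% of the libraries of each group, and means and SDs are over libraries with at least 20 reads.

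Groups, replicates and runs came from the labels and library names, 59 groups in 18 runs. Each comparison used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on methylated and unmethylated counts, with 1 library size for both counts of a library. The dispersion came from at most 1000 sites between 10% and 90% methylation. A site was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of group means of at least 5 points. The run was a term in the ligation comparisons of week 3 and day 3 in ganglion and of week 3 in cord, the diet in those of diet animals and in prefrontal cortex, and the weeks of diet in the diet effects. The comparisons, tests, naming rule and most alternatives were fixed before the data were examined; alternatives chosen after seeing the data are named in the closing section. Both edgeR and limma 3.58.1 were tested on simulated data. With 100 sites changed by 10 points, edgeR recovered 61% at the size and depth of the week 3 comparison and 41% at those of the RG108 comparison. With 100 changed by 20 points it recovered 91% and 81%. Of changes of 10 points it recovered 64% for day 3 ganglia, 36% for paclitaxel in cord, 19% for fetal ganglia, 8% for diet in ganglion and 5% for ganglion against cord. Of the limma calls in the simulated fetal comparison 35.77% were false.

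Named sites are the 5 largest gains and 5 largest losses at week 3 and the 2 and 2 largest elsewhere, the rule set for the case that no gene names could be had for the build. The diet effect is an F test over 3 diets, and its gains and losses follow the largest difference between diets. The test of week 3 sites in other comparisons took a mean over the sites per library, signed by the week 3 direction, with an exact two-sided permutation test or 100000 resamples where a group had 10 or more libraries. The direction toward other tissues was compared with 10000 random lists matched on methylation and size of difference, using sites called without run 64. The slopes on tissue differences, the matched lists of day 3 and cord sites, the sign flips over pairs and the averages over rats were not among the comparisons fixed in advance and were added after seeing the data. Mixing spleen libraries into ganglion libraries by simulation at shares of 0.05, 0.1 and 0.2 returned slopes of 0.0516, 0.1048 and 0.2076.

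Alternatives were coverage minimums of 10 and 50 reads, no minimum difference, limma on log ratios with a pseudocount of 1, a library size of its own for each of the 2 counts, the authors' adjustment, replicate numbers as a block, single runs, single diets or durations, and each library left out in turn. Permutation tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. By protocol the sham operation was on the other side, so ligated and sham libraries of the same number were taken as a pair from one rat in the ligation comparisons of ganglion and cord. The labels do not state this. The reported edgeR fits had no term for the pair. Pairs were used in the replicate block, the swaps of sides, the sign flips and the slopes. The sham library that correlated best with a ligated one had its number in 9 of 11 pairs at week 3, 6 of 6 at day 3, 6 of 8 in ganglia of diet animals, 3 of 3 with control siRNA, and 6 of 6 and 8 of 9 in cord, with correlations up to 0.79 (median 0.23) at week 3 and 0.09 or less in ganglia of diet animals. Rats with 2 ganglia were read from library names; at each time 4 of 6 ganglia L5 matched best with the L6 of their digit. Ganglion and cord of rats without surgery carry the same 3 animal numbers and were paired in the replicate block, not in the reported fit. There 3 of 3 ganglia were best matched by the cord of their number, with correlations of 0.01 to 0.05. In the comparisons of RG108, paclitaxel and Gadd45a siRNA a shared number was not taken as a pair. Gene lists and cell type markers were not analysed here, and no gene annotation of the build was used here.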

Results

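DNA methylation was measured at CCCGGG sites in 202 rat libraries by digital restriction enzyme analysis of methylation, in which SmaI cuts unmethylated sites and XmaI then cuts the methylated ones, so that each read carries the state of its site. There were 98 libraries of dorsal root ganglion, the sensory ganglion of a spinal nerve, 43 of spinal cord, 25 of prefrontal cortex, 18 of spleen and 18 of liver. Ganglia after spinal nerve ligation, a tight tie on a lumbar nerve that models neuropathic pain, were compared with sham ganglia, by protocol from the other side, at week 3 (11 libraries each) and at day 3 (6 each). Other ganglia came from rats given RG108, decitabine, paclitaxel, Gadd45a siRNA or control siRNA, from rats on 3 diets, and from fetal and neonatal rats. Total reads per library ranged from 883254 to 118920131, and 13780 to 75349 of the 151928 listed sites had at least 20 reads. All positions are in build rn4. No gene annotation of that build was used here, so sites are named by position and not by gene.

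The question at week 3 was whether an injured nerve changes methylation in its ganglion. In ligated ganglia 34 sites were more methylated and 11 were less methylated than in sham ganglia, among 21312 tested sites. Most gains, 29 of 34, lay at sites below 20% methylation in sham ganglia, whereas all 11 losses lay above that level. Of all tested sites 59.8% lay below 20%, and a site below 5% cannot lose 5 points. The largest loss was at chromosome 5 position 48461527, where methylation was 48.1% ± 14.4 (SD, n = 10) after ligation and 72.9% ± 12.9 (SD, n = 11) in sham ganglia, with a median of 70 reads per library (range 14 to 174). The largest gain was at chromosome 2 position 180883997, from 52.8% ± 15.0 (SD, n = 11) to 66.9% ± 12.9 (SD, n = 11), with a median of 1277 reads per library.

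The other named gains at week 3 were at chromosome 16 position 50570572 (42.3% to 56.4%), chromosome 19 position 52585824 (15.3% to 26.6%), chromosome 6 position 99169462 (54.1% to 65.3%) and chromosome 18 position 79461765 (13.3% to 23.8%). The other named losses were at chromosome 1 position 247168116 (54.02% to 38.59%), chromosome X position 90176683 (37.95% to 23.13%), chromosome 2 position 176201768 (40.02% to 26.13%) and chromosome 8 position 62663717 (70.5% to 56.9%). Adjusted p values of these 10 sites in the quasi-likelihood test of edgeR ran from 0.00574 to 0.0482, and each differed in its direction in 7 to 11 of the 9 to 11 measured pairs. With the replicate number as a block, which pairs ligated and sham ganglia, 242 sites were called (146 gains and 96 losses), among them all 45. Gains were 75.6% of the called sites as reported, 38.5% with a library size of its own for the methylated and unmethylated counts, and 6.4% with the authors' adjustment.

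The 11 pairs of week 3 came from 3 sequencing runs, and the pairs of run 64 stood apart from those of runs 4 and 10. Names of run 10 appear to give ganglia L5 and L6 of the same 3 rats, so the 11 pairs may come from 8 rats; with such ganglia summed 392 sites were called, 193 of them gains. At the 60 sites called without run 64, the ligated ganglia of the 9 pairs of runs 4 and 10 differed from their sham partners by 7.27 to 11.0 points in the direction of the call, as the selection of sites from these pairs favours. The 2 pairs of run 64 differed by 1.11 and -0.66 points, while differences between 2 sham libraries of one run ranged from -1.31 to 2.05 points. Taken alone, run 4 gave 164 called sites, and edgeR called 0 in run 10 (1002 sites at an unadjusted p under 0.05) and 0 in run 64 (388 sites). Without a run term edgeR also called 0 (1220 sites). With all runs and the run term 1745 sites had an unadjusted p under 0.05, and limma called 22. Without the 3 libraries of run 10 that lay apart from the others of their run (SNL 008, SNL 009 and sham 008), 453 sites were called, 43 of the 45 among them.

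**Figure D1:**
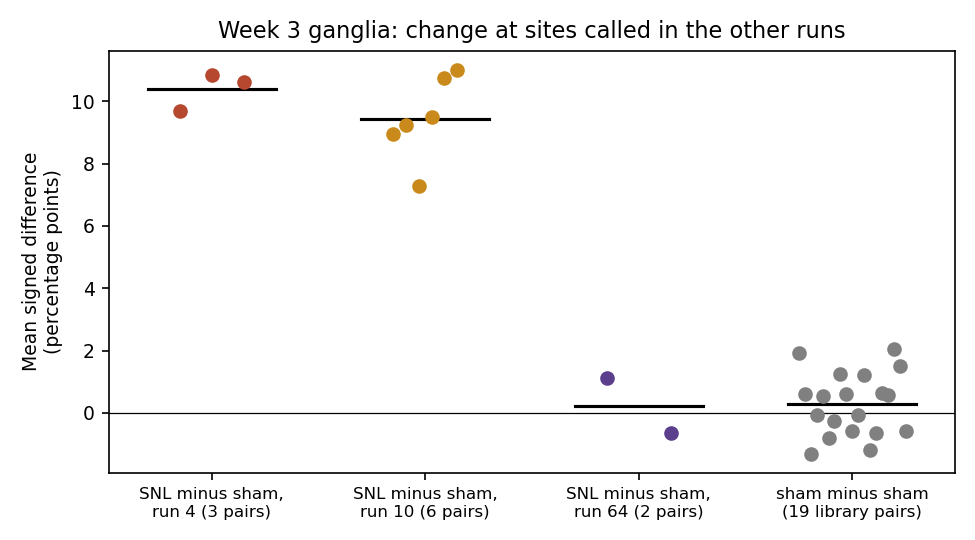
Mean signed difference in percentage points (vertical axis) at sites called without run 64, 1 point per pair of ganglia in 3 sequencing runs, with the mean as a line; grey points are differences between 2 sham libraries of one run. The pairs of run 64 sit at 1.11 and -0.66, inside the range of the sham libraries (-1.31 to 2.05), and the pairs of runs 4 and 10 at 7.27 and above.

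At day 3 the same contrast gave far more sites: 897 gains and 367 losses among 22134 tested sites. Gains were spread over sites of low (47.2%) and intermediate (52.5%) methylation in sham ganglia, and 269 of the 367 losses were at intermediate sites, between 20% and 80%. Of all tested sites 59.6% were low and 18% intermediate, so called sites were more often intermediate. The largest named gain, at chromosome 19 position 52585741, went from 14.3% ± 1.88 (SD, n = 6) to 36.5% ± 16.5 (SD, n = 6), with a median of 202 reads. Chromosome 10 position 13582246 went from 41.2% ± 21.9 to 62.5% ± 17.2 (SD, n = 6 each). The largest losses were at chromosome 20 position 21193676 (69.1% ± 8.30 to 42.7% ± 3.86, SD, n = 5 each) and chromosome 17 position 78610679 (70.5% ± 10.6 to 47.9% ± 10.3). All 34 gains of week 3 and 10 of its 11 losses were also called at day 3, against 1.43 and 0.193 for lists drawn independently.

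The day 3 libraries came from 2 runs. Run 10 alone gave 1376 sites and run 9 alone 150, but run 9 had 7736416 to 9369808 reads per library and run 10 had 8148126 to 27539439, so these counts also depend on read number. At week 3 sites both runs differed in the week 3 direction in 3 of 3 pairs, by 8.36 points in run 9 and 15.37 in run 10. The largest named gain, at chromosome 19 position 52585741, differed by 9.14 points in run 9 and 35.15 in run 10. Chromosome 10 position 13582246 differed by 25.47 points in run 9 and 17.19 in run 10. The library names appear to give ganglion L6 for run 10 and L5 for run 9, so ganglion and run cannot be told apart. Both runs number the ganglia 1 to 3, so the 6 pairs may come from 3 rats. With the authors' adjustment 365 sites were called and the share of gains rose from 71.0% to 97.8%; run 9 then gave 147 sites and run 10 gave 5. A test of whether the ligation difference itself changed from day 3 to week 3 called 0 sites with edgeR (742 sites at an unadjusted p under 0.05) and 0 with limma.

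The same ligation was made in 2 further sets of rats at week 3. In rats on the 3 diets (8 ligated and 9 sham ganglia), 66 sites gained and 59 lost methylation, and 7 of the 10 measured week 3 losses and 2 of the 31 measured gains were among them, against 0.0243 and 0.101 for independent lists. The site at chromosome 5 position 48461527 again lost methylation, from 57.8% ± 12.1 (SD, n = 9) to 32% ± 12.2 (SD, n = 8). The largest loss was at chromosome 3 position 91937992 (89.3% ± 7.84 to 62.9% ± 39.4, SD, n = 8 each). The named gains were at chromosome 1 positions 251018837 (11.9% to 36.8%) and 139479309 (47% to 63.8%). Of the week 3 sites, 39 of 41 differed in the same direction as before, by 5.43 points on average (exact two-sided permutation test, p = 0.000699, adjusted p = 0.00489 over 14 comparisons). That test takes the libraries as separate; by sign flips over the 8 pairs, 7 of them above 0, p was 0.0156 and adjusted p 0.109. In animal 21 the ligated ganglion had a signed mean of -3.8 and the sham ganglion one of 1.55, a difference of -5.35 points. The other ligated ganglia lay between 0.53 and 2.92 and the other sham ganglia between -6.16 and -4.28, so each ganglion of animal 21 lay apart from its own group. In rats given control siRNA (3 and 3), 0 sites gained and 29 lost methylation, 6 of them week 3 losses. The largest loss, at chromosome 16 position 59736704, went from 78.4% ± 8.30 to 49.5% ± 1.47 (SD, n = 3 each). The other named loss was at chromosome 3 position 157371104 (96.1% to 71.9%). In these rats 30 of 44 week 3 sites had the same direction, by 3.88 points (exact permutation p = 0.2, the smallest possible being 0.1).

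Counts in both sets changed when 1 animal or library was left out, which also leaves fewer libraries to test. Among diet animals the count was 72 without animal 13, 62 without 15, 82 without 16, 49 without 17, 48 without 20 and 296 without 21; the share of gains was 52.8% as reported, 9.2% with separate library sizes and 16.0% with the authors' adjustment. In the siRNA set the count was 8, 3 or 1 without ligated ganglion 1, 2 or 3, and 5, 17 or 7 without sham ganglion 1, 2 or 3; with the animals paired it was 10. No site was called for a dependence of the ligation difference on the diet in edgeR (0 called, 995 sites at an unadjusted p under 0.05; limma 0), although leaving out animal 13, 18 or 19 gave 4, 61 or 3 sites.

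Week 3 sites were also read in libraries of purified ganglion neurons and of the material before purification, with 2 ligated and 1 sham library of neurons and 1 of each for the input, too few for a test. At gain sites the mean methylation was 26.9% and 20.7% in neurons after ligation and 14.0% in sham neurons; the input gave 19.5% and 13.7%. At loss sites the neurons gave 42.8% and 37.9% after ligation and 60.7% in sham, and the input 35.4% and 58.9%. All 40 measured sites differed in the direction of week 3 in neurons, by 11.1 points on average, and 41 of 42 in the input, by 9.39 points.

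**Figure D2:**
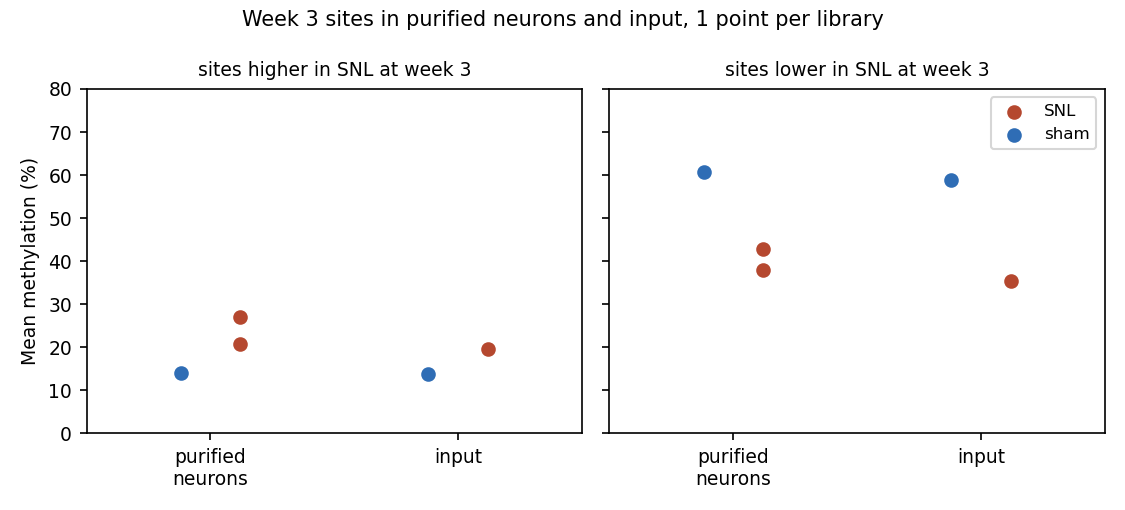
Mean methylation in percent (vertical axis) at week 3 gain sites (left) and loss sites (right), 1 point per library of purified neurons and of the input. Ligated neurons sit at 26.9% and 20.7% against 14.0% in sham neurons at gain sites, and at 42.8% and 37.9% against 60.7% at loss sites.

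Differences after ligation were compared with those between ganglion and the other tissues of rats without surgery. Of the day 3 sites that could be compared, 1129 of 1178 (95.8%) changed from ganglion toward spleen, 98.4% of gains and 89.7% of losses. Random lists of tested sites matched on sham methylation and on the size of the spleen difference gave 90.2% (p = 0.0002, the smallest these lists allow; adjusted p = 0.0006 over 6 references). The shares toward liver (67.2% and 62.3% in matched lists) and cortex (55.8% and 50.8%) were also higher, and those toward cord (50% and 53%), fetal (44.8% and 49.2%) and neonatal ganglion (40.1% and 47.1%) lower, with adjusted p values up to 0.0398. These lists, like those of week 3 and cord below, were not matched on the size of the ligation difference, by which sites were called, so part of such a distance can come from that. Across all compared sites, called or not, the ligation difference of each pair was then regressed on the differences of spleen, liver, cord and cortex from ganglion. The spleen slope at day 3 averaged 0.153 ± 0.054 (SD, n = 6 pairs), above 0 in 6 of 6 pairs (exact two-sided sign-flip permutation p = 0.0312, the smallest possible; adjusted p = 0.0858 over 11 comparisons). Averaged over the ganglia that may share a rat, it was above 0 in 3 of 3 rats (exact permutation p = 0.25, the smallest possible). It was 0.112 ± 0.041 in run 9 and 0.195 ± 0.019 in run 10 (SD, n = 3 each), while the liver slope averaged 0.001.

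At week 3 the spleen slope averaged 0.063 ± 0.040 (SD, n = 11 pairs; permutation p = 0.00195, adjusted p = 0.0215), above 0 in 10 of 11 pairs. Averaged over ganglia that may share a rat, it was 0.059 ± 0.041 (SD, n = 8 rats, exact permutation p = 0.0156, adjusted p = 0.114). It passes by pairs. By rats the smallest possible p of this exact permutation test is 0.00781. With the other p values as they were, that could not pass after adjustment over 11 comparisons, so the adjusted test by rats decides nothing. By run it was 0.079 in run 4, 0.075 in run 10 and 0.004 in run 64. In the 8 pairs of diet animals it averaged 0.043 ± 0.032, with animal 21 at -0.0253, and in the 3 control siRNA pairs -0.015 ± 0.013. Without animal 18, whose ganglia matched other tissues of animal 16, it averaged 0.04 in diet animals. In decitabine ganglia against their control it averaged 0.084 ± 0.024 (SD, n = 3, exact permutation p = 0.1, the smallest possible). Single decitabine controls ranged from -0.0787 to 0.0563. RG108 gave -0.038, paclitaxel 0.006 and Gadd45a siRNA 0.018 in ganglia. Of the sites called at week 3 without run 64, 48 of 56 (85.7%) pointed toward spleen, 100% of gains and 52.9% of losses. The total did not exceed the 89.2% of random lists matched on sham methylation and on the size of the spleen difference (permutation p = 0.47). These sites pointed toward fetal ganglion in 12 of 56 cases (21.4%) against 45.2% in matched lists (p = 0.0002, the smallest these lists allow; adjusted p = 0.0012 over 6 references). Toward neonatal ganglion the count was 14 of 56 against 43.2% (p = 0.0084, adjusted p = 0.0252). For cord, cortex and liver the adjusted p was 0.276, 0.858 and 0.773. These calls depended on settings. With sites of at least 10 points 5 of 21 pointed toward neonatal ganglion (adjusted p = 0.126). With the authors' adjustment 82.1% pointed toward spleen against 68.9% in matched lists (adjusted p = 0.0228). With the list of the replicate block 39.9% pointed toward cord against 49.3% (adjusted p = 0.002). Taken by single sites, 7 of 39 measured gains without run 64 were also called gains in fetal ganglia (1.91 for independent lists) and 8 were losses there (2.07); of 17 measured losses 0 were fetal losses (0.901) and 9 fetal gains (0.831). Of 783 measured day 3 gains 206 were fetal gains (38.5 for independent lists) and 115 fetal losses (41.7), and of 322 day 3 losses 16 were fetal losses (17.2) and 51 fetal gains (15.8).

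**Figure D3:**
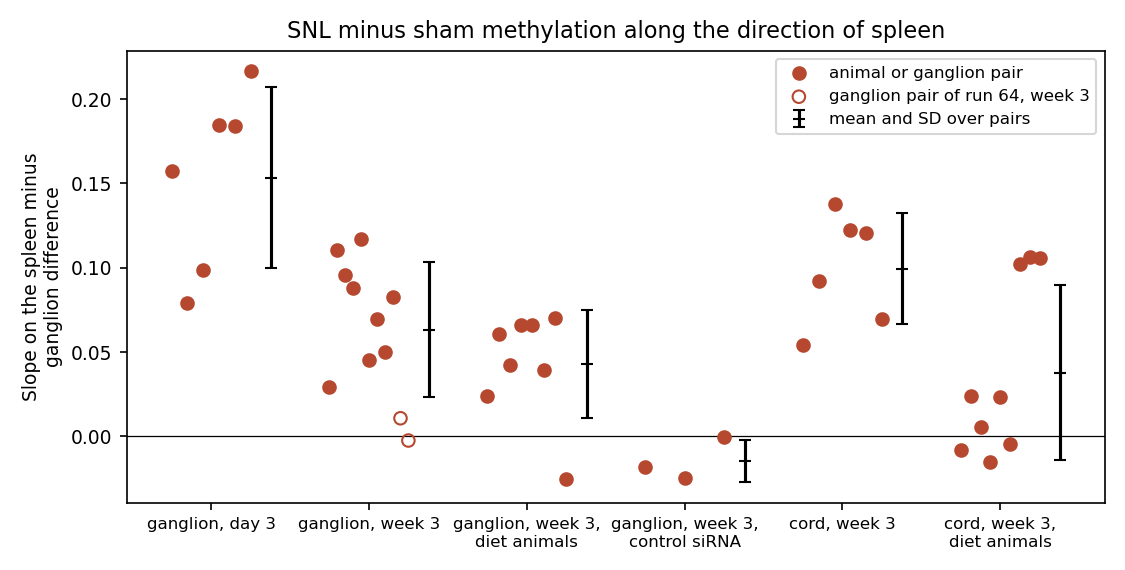
Slope of the ligated minus sham difference across sites on the spleen minus ganglion difference (vertical axis, no unit), 1 point per pair of libraries, with mean and SD over pairs in 6 sets. Day 3 ganglia average 0.153, week 3 ganglia 0.063 (open points: run 64) and control siRNA ganglia -0.015.

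The contrast was repeated in spinal cord at week 3 (6 and 6 libraries). In cord 311 sites gained and 416 lost methylation among 19363 tested sites, and 177 of the gains and 181 of the losses were also called in day 3 ganglia, against 13.9 and 7.63 for independent lists. Week 3 ganglia shared 13 of 31 measured gains with cord (0.524 for independent lists) and 1 of 10 measured losses (0.223). The largest gain, at chromosome 1 position 161395793, went from 23.0% ± 2.53 to 45.5% ± 4.53 (SD, n = 6 each), and a further one at chromosome 5 position 75846228 from 31.0% to 49.1%. The latter had a median of 39 reads and differed by 2.72 points in run 28 and 28.36 in run 64. The largest losses were at chromosome 8 position 48225155 (83.2% ± 8.02 to 53.2% ± 4.75, SD, n = 5 each) and chromosome 15 position 22828878 (51.1% to 23.8%). Of the called sites 610 of 698 (87.4%) changed from cord toward spleen, 79.4% toward liver and 71.7% toward ganglion, against 80.3%, 67.2% and 59.3% in lists matched on sham methylation and size of the tissue difference (p = 0.0002 for each, the smallest these lists allow). The slope on the spleen minus ganglion difference averaged 0.099 ± 0.033 (SD, n = 6 pairs), above 0 in 6 of 6, and that on the cord difference -0.133. Week 3 sites of the ganglion had the same direction in 38 of 41 cases, by 5.05 points (exact permutation p = 0.00216, adjusted p = 0.00756). By sign flips over the 6 pairs, all above 0, p was 0.0312, the smallest possible, and adjusted p 0.109. With week 3 sites of at least 10 points the difference was 3.24 points (exact permutation p = 0.0563, adjusted p = 0.197). Run 28 alone gave 68 sites, run 64 335, and a fit without a run term 133. The share of gains was 42.8% as reported, 28.8% with separate library sizes and 80.3% with the authors' adjustment.

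Cord of the diet animals (9 and 9) gave 15 gains and 57 losses, but the outcome depended on the run. All ligated libraries and the sham libraries of animals 19 to 21 were in run 50, and the other 6 sham libraries in run 49. Ligated minus sham mean methylation was 2.65 points in the 3 pairs within run 50 and -1.62 points in the 6 pairs across runs. The 3 pairs of run 50 alone gave 2496 gains and 6 losses, run 50 with all its libraries gave 3031 gains and 9 losses, and run as a further term gave 92 gains and 11 losses, with 8, 11 and 4 sites in common with the reported list. The largest gain of the reported list was at chromosome 2 position 118825097 (54.5% ± 29.03 to 94.9% ± 3.11, SD, n = 7 each), followed by chromosome 4 position 9800703 (64.7% to 95.6%). The named losses were at chromosome 13 position 86957097 (41.7% to 16.0%) and chromosome 9 position 8475590 (59.3% to 43.2%); the former differed by 1.63 points, in the other direction, in the 3 pairs of run 50. At week 3 ganglion sites the direction was the same in 38 of 41 cases, by 2.02 points over all libraries, 3.34 points within run 50 and 1.36 points across runs; by sign flips over the 9 pairs the adjusted p was 0.0547.

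Knockdown of Gadd45a, a stress-response gene linked to DNA demethylation, was compared with control siRNA in ligated ganglia (5 and 3). It gave 8 gains and 6 losses, led by chromosome 10 position 38038914 (46.3% ± 9.45, n = 3, to 84.5% ± 17.3, n = 5, SD) and chromosome X position 160442921 (66.6% ± 11.3, n = 3, to 41.4% ± 15.1, n = 5, SD). The others named were at chromosome 1 position 187720577 (30.2% to 49.4%) and chromosome 18 position 78252307 (54.7% to 39.5%). At week 3 sites the knockdown libraries differed by 0.98 points from control siRNA in the direction of ligation, less than the SD of 1.26 (exact permutation p = 0.304). The difference was 0.32 without control library 1, 1.48 without control library 2 and 1.54 without knockdown library 2. The count was 8 or 5 without knockdown library 1 or 3, and 6, 3 or 4 without control library 1, 2 or 3. The share of gains was 57.1% as reported, 7.1% with separate library sizes and 21.7% with the authors' adjustment, and the last 2 turned the balance to losses.

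RG108 and decitabine both inhibit DNA methyltransferases, the enzymes that add methyl groups to DNA. RG108, given at 10 µg, was compared with vehicle (3 and 3) and left 13 sites more methylated and 4 less methylated. The named gains were at chromosome 10 positions 107061971 (51.2% ± 6.48 to 78.1% ± 4.98) and 107061813 (52.44% to 79.25%), and the named losses at chromosome 2 position 204484225 (66.9% ± 33.7 to 14.1% ± 6.63) and chromosome 4 position 168429057 (81.1% to 62.1%). Decitabine against its control (3 and 3) gave 32 gains and 10 losses. Its named gains were at chromosome 12 position 14796740 (48.3% ± 19.0 to 94.0% ± 1.28) and chromosome 8 position 51013906 (9.71% to 46.2%), and its named losses at chromosome 18 position 77179978 (69.08% to 24.01%) and chromosome 10 position 105501938 (68.9% ± 27.4 to 42.9% ± 5.97; SD, n = 3 for all of these). The doses of the 2 compounds were not compared. Across sites the 2 treatments' differences correlated at -0.13, and sites are not independent replicates.

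These counts changed when 1 library was left out, which also leaves fewer libraries to test. RG108 gave 6, 0 or 9 sites without RG108 library 1, 2 or 3, and 9 or 0 without vehicle library 1 or 2. Decitabine gave 17, 11 or 6 without treated library 1, 2 or 3, and 8, 10 or 5 without control library 5, 6 or 7; limma called 192 sites. For decitabine the share of gains was 76.2% as reported, 43.2% with separate library sizes and 59.5% with the authors' adjustment. At week 3 sites RG108 differed by -2.73 points and decitabine by 6.09 points (exact permutation p = 0.2 and 0.1, the latter the smallest possible). Single controls weighed on both: vehicle library 3 lay at 6.33 and the others at 0.55 and 0.04, and decitabine control 7 lay at 2.95 and the others at 9.16 and 10.69. Without these 2 libraries the differences were -0.72 and 3.76 points.

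Paclitaxel, a chemotherapy drug that causes painful neuropathy, was given at 2 mg/kg and compared with its control (3 and 3 ganglia). It gave 10 gains and 7 losses; the named gains were at chromosome 2 position 204484225 (25.3% ± 19.1 to 66.9% ± 19.2, SD, n = 3 each) and chromosome 20 position 3701319 (32.8% to 55.7%), and the named losses at chromosome 20 position 49891117 (100% to 78.5%) and chromosome 12 position 28790809 (25.5% to 8.35%). In cord (2 and 3) edgeR called 0 sites, with 1129 sites at an unadjusted p under 0.05, and limma called 8. The ganglion count was 0, 0 or 2 without paclitaxel library 1, 2 or 3 and 1 or 1 without control library 2 or 3, while cord gave 1 site without paclitaxel library 1 and 4 without control library 1. The share of gains in ganglion was 58.8% as reported and 33.3% with separate library sizes. Week 3 sites had the same direction in 17 of 42 cases in ganglion, by -1.06 points (exact permutation p = 0.6; from -1.96 to 0.06 without 1 library, the latter without paclitaxel library 3), and in 25 of 42 in cord, by 0.63 points (p = 0.1, the smallest possible, so that this test could not pass).

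Diets with 0.1, 2.1 or 10.5 ppm folate (deficient, regular and enriched, with 3, 28 or 140 µg/kg vitamin B12) for 4 or 7 weeks asked whether the supply of methyl donors changes methylation. At 7 weeks the ganglia and cords were the sham libraries of the ligation comparisons, and the cortices came from ligated rats. In these tissues time on the diet and surgery differ together. Differing sites numbered 21 in ganglion, 11 in cord, 1 in prefrontal cortex, 3 in spleen and 1 in liver. Chromosome 2 position 204484225 was among those of ganglion (63.2% ± 28.9 deficient, 51.1% ± 23.4 regular, 31.0% ± 25.7 enriched; SD, n = 6 each) and spleen (71.3% ± 24.1, 59.2% ± 19.5 and 33.6% ± 19.0; SD, n = 6 each). Chromosome 15 position 3403 was among those of ganglion (92.5% ± 3.49, 93.3% ± 3.49 and 65.6% ± 43.6; SD, n = 6 each) and cord (93.7%, 92.9% and 66.3% ± 42.4). Other named sites were chromosome 2 position 251051514 and chromosome 10 position 105501636 in ganglion, chromosome 15 position 3654, chromosome 13 position 86957097 and chromosome 10 position 105501938 in cord, chromosome 8 position 124554902 in spleen and chromosome 12 position 32557404 in liver. At chromosome 15 position 3403 the mean correlation over animals between tissues of the same animal was 0.99. At chromosome 2 position 204484225 and chromosome 15 position 3654 it was 0.95. At chromosome 10 positions 105501636 and 105501938 it was 0.94 and 0.96. Ganglion, cord and spleen carry the same animal numbers, so calls at these sites in more than 1 tissue are not independent. Chromosome 1 position 186467982 was called for diet in ganglion, cord, cortex and spleen and also with decitabine. In cortex and spleen regular-diet animals averaged 6.36% ± 9.87 and 7.60% ± 11.7 (SD, n = 6 each) and the other diets under 1%. Over animals of 7 weeks, those on the regular diet included, it ranged from 0.0% to 0.2% in cortex and from 0.0% to 0.3% in spleen. The higher regular-diet means thus came from animals of 4 weeks alone. These tissues carry the same animal numbers.

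The diet counts were small and unstable. Limma called 0 sites in all 5 tissues; at an unadjusted p under 0.05 edgeR had 1289 sites in ganglion, 1328 in cord, 816 in cortex, 739 in spleen and 976 in liver. In ganglion the count was 0 without animal 14, 15, 16 or 20, 1 without 18, 9 without 13, 13 without 3, 10, 17 or 21, 41 without 6 and 51 without 2. Cord gave 6 without animal 14 and 7 without animal 16. Cortex gave 33 without animal 7, 25 without 6, 14 without 2, 5 without 14, 4 without 8, 3 without 4, 17, 19 or 21, and 2 without 1, 3, 15, 16, 18 or 20. Spleen gave 7 without animal 2, 6 without 18, 5 without 10 and 1 without 3 or 14. Liver gave 9 without animal 3, 7 without 10, 6 without 6 or 7, 4 without 4 or 8, 3 without 2 or 17, and 2 without 1, 9, 15, 18, 19 or 20. The ganglia labelled as animals 16 and 18 matched each other's other tissues; both were on the enriched diet, and without them the ganglion count was 0.

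Prefrontal cortex of 8 ligated animals at 7 weeks of diet was compared with that of 9 animals without surgery at 4 weeks. It gave 47 gains and 63 losses, but surgery, age, time on the diet and run differ together in this contrast. The named gains were at chromosome 5 position 151426900 (26.5% ± 23.0, n = 9, to 60.6% ± 8.68, n = 8, SD) and chromosome 7 position 9863053 (41.5% to 74.5%). The named losses were at chromosome 7 position 38803068 (54.7% to 16.0%) and chromosome 15 position 3141 (70.63% to 34.02%). The share of gains was 42.7% as reported, 65.6% with separate library sizes and 69.8% with the authors' adjustment, and run 90 alone gave 182 gains and 19 losses. Week 3 ganglion sites differed by -0.09 points in cortex (exact permutation p = 0.774), and by -0.18 to 0.04 points without 1 animal.

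Age and tissue gave larger differences than ligation at week 3. Fetal ganglia had 885 sites more and 948 less methylated than adult sham ganglia (2 and 2), and neonatal ganglia 704 more and 737 less (2 and 2). The lists shared 668 gains and 596 losses with 0 sites in opposite directions, but both use the same 2 sham libraries. Across sites the differences correlated at 0.92, and at 0.6 in simulated libraries without any change. Chromosome 12 position 42366142 was at 88.4% ± 1.27 in fetal, 85.6% ± 2.05 in neonatal and 28.2% ± 3.83 in adult ganglia (SD, n = 2 each). Chromosome X position 22783940 was at 28.2% ± 0.79, 32.1% ± 2.05 and 84.8% ± 3.58, and chromosome 4 position 65883836 at 23.8%, 25.6% and 75.8%. Further gains were at chromosome 16 position 79553490 in fetal ganglia (9.01% to 61.9%) and chromosome 2 position 32652046 in neonatal ganglia (11.5% to 64.2%). The fetal and neonatal counts fell when 1 library was left out, which leaves 1 library in its group. The weight of that library cannot be told from the loss of a replicate. Gains in neonatal ganglia were 48.9% of called sites as reported and 62.1% with separate library sizes.

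Ganglion and cord of rats without surgery on the regular diet (3 and 3) differed at 1646 sites, 590 more and 1056 less methylated in ganglion. All ganglion libraries were in run 35 and all cord libraries in run 34, so tissue and run cannot be told apart in this contrast. Both tissues carry the same 3 animal numbers; this fit takes the libraries as separate, and with the number as a block, pairing the tissues, 1142 sites were called. The named sites were chromosome 8 position 112731166 (89.9% ± 4.40 in ganglion, 23.3% ± 8.52 in cord, SD, n = 3 each), chromosome 12 position 38157050 (67.5% and 1.45%), chromosome 8 position 73900303 (13.1% ± 12.9 and 87.1% ± 2.48, SD, n = 3 each) and chromosome 13 position 47753136 (11.4% and 79.7%). The count was 797, 487 or 464 without cord library 1, 3 or 7. Sites more methylated in ganglion were 35.8% of those called as reported and 14.2% with the authors' adjustment.

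**Figure D4:**
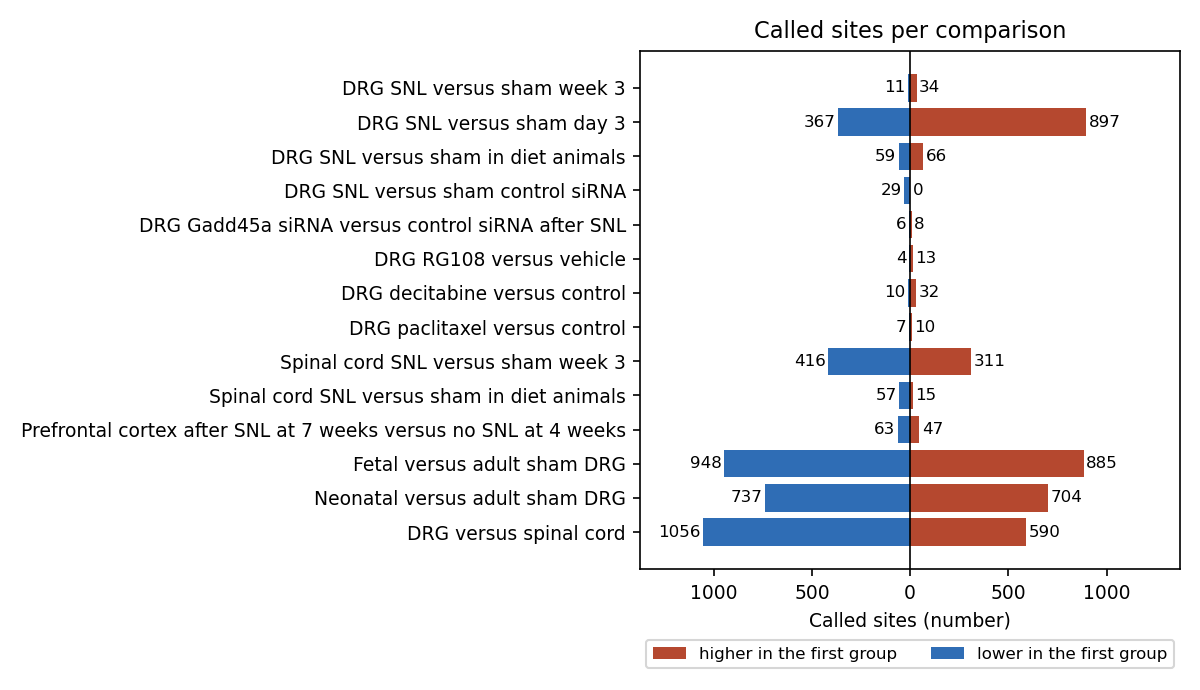
Number of sites called as more methylated (right) and less methylated (left) in the group named before "versus" in each comparison of 2 groups with at least 1 called site. Day 3 ganglia have 897 gains and 367 losses, week 3 ganglia 34 and 11.

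Mean methylation per library was compared in the 15 contrasts of 2 groups. None had an adjusted p under 0.05 in a permutation test, but 8 of the 15 have too few libraries to reach an unadjusted p of 0.05. Ligated ganglia averaged 31.9% ± 1.04 and sham ganglia 31.8% ± 1.42 at week 3 (SD, n = 11 each, two-sided permutation p = 0.779). Within runs 4, 10 and 64 the difference was 0.07, 0.19 and 0.19 points. With the authors' adjustment the week 3 difference was -0.77 points (permutation p = 0.0167, adjusted p = 0.125). In ganglia of diet animals it was 0.17 points as deposited and -0.38 with the adjustment (exact permutation p = 0.011, adjusted p = 0.125). At day 3 ligated and sham ganglia averaged 31.0% ± 0.84 and 30.6% ± 0.40 (SD, n = 6 each, exact permutation p = 0.325), with a difference of -0.01 points in run 9 and 0.77 in run 10. Decitabine libraries averaged 31.8% ± 0.42 against 31.0% ± 0.24 in controls (SD, n = 3 each, exact permutation p = 0.1, the smallest possible).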

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

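All tests of spleen slopes and of their differences were chosen after the slopes had been seen, as were the averages and splits over rats, and all tests of exchanged sides, of thinned reads, of ganglia without ligation and of the authors' adjustment, its unequal sizes included; the test of sites alike in spleen and ganglion was chosen before.

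Differences between sets in the ligation effect drew attention, each by a two-sided permutation test of the difference of spleen slopes. The slope was higher at day 3 than at week 3 by 0.09 (exact permutation p = 0.00162, adjusted p = 0.0167 over 11 tests), and within run 10, which holds both times, by 0.12 (p = 0.0119 for 3 and 6 ganglia). Taken as 3 and 3 rats, the latter gives p = 0.1, the smallest possible, so it decides nothing; with ganglia L6 alone, the only ones of day 3 in run 10, the difference was 0.128. Over all runs, averaged over ganglia that may share a rat, it was higher by 0.095 (3 and 8 rats, exact permutation p = 0.0121). It was lower with control siRNA than in runs 4 and 10 of week 3 (difference -0.091, p = 0.00455) and than at day 3 (-0.168, p = 0.0119 for 3 and 6 ganglia). By rats these gave p = 0.0119 (3 and 6) and p = 0.1 (3 and 3, the smallest possible), so the latter decides nothing. It was lower in ganglia of diet animals than in runs 4 and 10 (-0.034, p = 0.0388, adjusted p = 0.0475), but not by rats (8 and 6, exact permutation p = 0.0529). In cord it was lower in diet animals than in the other rats (-0.062, p = 0.0268, adjusted p = 0.0368), and within diet animals it was 0.105 inside run 50 and 0.004 across runs; with a shift term these were 0.043 and 0.051. Apart from the comparison within run 10, the sets differ in run as well, so that run and set cannot be told apart. In mean methylation or spleen slope no library or pair stood apart from its group in 15 sets tested; chance alone sets apart about 1 in 20. Sets of more than 10, week 3 ganglia among them, were not tested in this way.

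The first pattern weighed is that day 3 changes point from ganglion toward spleen. A shift of whole libraries toward more or less methylation is argued against, since with a term for it the slope stayed at 0.158 (SD 0.047 over 6 pairs). DNA of cells with a spleen-like profile in ligated ganglia is a candidate explanation, since the slope was also above 0 where spleen is less methylated (0.162, SD 0.033). A positive spleen slope was not limited to ligation against sham, since decitabine ganglia against their control averaged 0.084 (SD 0.024, n = 3). More liver-like or cord-like cells alongside are argued against, since the spleen slope exceeded the larger of these 2 slopes, that of liver, by 0.153 (SD 0.058). More cortex-like cells stay open: the spleen slope exceeded that of cortex by 0.141 in the mean and in 6 of 6 pairs, which is less than 2 SD of 0.071. A change of methylation inside ganglion cells was not tested.

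The second pattern is that the 2 week 3 pairs of run 64 lack the change of the other 9. Exchanged sides are argued against, since the lower of the 2 signed differences was -0.66 and the other 9 pairs lay at 7.27 or more. Too few reads are argued against as well, but only as a source of noise. The reads of each site were thinned to the fewest of these 4 libraries. The other 9 pairs still differed by 7.29 points or more (SD 0.93). Thinning leaves the expected difference unchanged, so it tests added noise alone, at sites called from these 9 pairs. A comparison of median reads had been chosen before but is not used, since the medians also follow how many sites pass 20 reads. Ganglia without ligation under ligation labels may explain the pattern: the higher difference, 1.11, lies within the range of sham libraries (-1.31 to 2.05). A ligation without effect in these 2 rats would look alike, and no biological explanation was tested.

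The third pattern is that the ganglia of diet animal 21 differ against the direction of the other 7 pairs. Exchanged labels of the 2 sides stay open: the signed difference was -5.35 points, nearer to 0 than the smallest of the other pairs (5.99), but by less than their SD of 0.7. An exchange would change the counts, the direction and the slope given for ganglia of diet animals; other explanations were not tested.

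The fourth pattern is that most day 3 gains of run 10 are not called with the authors' adjustment. A lowering of all 3 ligated libraries by the adjustment was not seen. Against their sham partners it moved them by 0.53, 0.4 and -0.064 in log odds, so 2 of the 3 were raised. The mean of 0.287 lay below the SD of 0.311. Whether the gains set the adjustment stays open, since sites alike in spleen and ganglion differed by 0.47 points with an SD of 1.05. Unequal adjustment of libraries of one group is a candidate explanation: the SD of mean methylation over the 3 ligated libraries was 2.27 points with the adjustment and 0.3 points as deposited.

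Other splits of the same libraries tested whether chance could give as many sites. Chance is argued against for week 3 ganglia (45 sites, at most 0 in the other 39 splits by swapping sides within animals). The same holds for day 3 ganglia with 6 separate pairs (1264 and 925) and week 3 cord (727 and 372), with all 32 splits run. It also holds for ganglia of diet animals (125 and 97) and prefrontal cortex (110 and 91). Week 3 ganglia, ganglia of diet animals and cortex had 40 splits of 1024, 256 and 4000 possible, so splits not run could give more sites. With ganglia of a possible rat swapped together, week 3 gave at most 0 in 39 other splits, and day 3 at most 0 in 3, too few to tell. The highest other counts came from swapping 1 animal at day 3 and 1 in week 3 cord, and animals 15 and 21 among the ganglia of diet animals. Chance cannot be excluded for cord of diet animals (72 and 153, with 3 of 40 splits as large), where the splits as large swap the animals whose sham library was in run 49, nor for Gadd45a siRNA (14 and 25, 6 of 56). It cannot be excluded for diet in ganglion (21 and 50, 9 of 24), cord (11 and 11, 2 of 24), cortex (1 and 89, 17 of 24), spleen (3 and 15, 9 of 24) or liver (1 and 7, 14 of 24), with 89 sites in a split of cortex pointing to a structure of the samples that was not identified. For the ligation effect by diet (0 and at most 3 in other splits) and by time (0 and at most 134, again a structure not identified) the splits decide nothing, since with 0 sites every split is as large (24 of 24 and 12 of 12). The splits are too few to tell for RG108 (17 and 2), decitabine (42 and 18), paclitaxel (17 and 15), ganglion against cord taken as separate libraries (1646 and 0) and control siRNA (29 and 3), each 1 of 10.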

How the results depend on the processing

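The authors' adjustment, the settings without run 64, those without 3 libraries of run 10, those by run in cord of diet animals, the list of the replicate block and the sign flips over pairs were chosen after seeing the data. Of 339 counts under alternatives 154 stayed within 1.5 times the reported one, 152 moved and 33 changed their balance of gains and losses; of 421 values of named sites 337 kept direction and call, 82 lost the call and 2 reversed. The causes were not tested. Without a minimum difference the counts were 89 at week 3, 1942 at day 3, 127 in cord of diet animals, 285 in prefrontal cortex and 2 for diet in liver. With 10 reads they were 24 for Gadd45a, 7 for paclitaxel in cord, 1802 fetal (906 gains), 1406 neonatal (709 gains), and for diet 7 in cortex, 5 in spleen and 12 in liver. With 50 reads they were 5 for Gadd45a (2 gains), 11 for paclitaxel in ganglion, 69 in cortex, and for diet 0 in ganglion and 1 in spleen. Limma called 22 at week 3, 46 in ganglia of diet animals, 6 for Gadd45a, 192 for decitabine, 34 and 8 for paclitaxel in ganglion and cord, 429 in week 3 cord, 19 in cord of diet animals, 62 in cortex and 0 for diet in all 5 tissues. With own library sizes the counts were 96 at week 3 (37 gains), 152 in ganglia of diet animals (14), 18 for control siRNA (0), 42 for Gadd45a (3), 37 for decitabine (16), 15 and 1 for paclitaxel in ganglion (5) and cord (1), 364 in week 3 cord (105), 168 in cord of diet animals (31), 128 in cortex (84), 1690 fetal (862), 1331 neonatal (826) and 3 for diet in cortex. With the authors' adjustment they were 125 at week 3 (8 gains), 365 at day 3 (357), 147 and 5 in its runs 9 and 10, 163 in ganglia of diet animals (26), 12 for control siRNA (0), 23 for Gadd45a (5), 943 in week 3 cord (757), 233 in cord of diet animals (68), 149 in cortex (104), 1322 neonatal (773) and 2 for diet in liver. With the replicate block, which pairs animals for ligation and for ganglion against cord, they were 242 at week 3 (340 without run 64, 546 with the authors' adjustment, 44 of them gains), 10 for control siRNA, 1 for Gadd45a, 0 for RG108 and 1 for paclitaxel in ganglion. By run or time they were 0 at week 3 without a run term, 164, 0 and 0 in its runs 4, 10 and 64, 453 without SNL 008, SNL 009 and sham 008, 392 with ganglia of an animal summed (193 gains), 713 at day 3 without a run term, 150 in its run 9, 133 in week 3 cord without a run term, 68 and 335 in its runs 28 and 64, and 201 in run 90 of cortex (182 gains). In cord of diet animals they were 2 on the regular diet, 2502 in the 3 pairs of run 50, 3040 in run 50 and 103 with run as a further term, and chromosome 13 position 86957097 differed by 1.63 and 7.7 points in the first pair of run 50 settings. For diet they were 0 in ganglion at 4 weeks and without animals 16 and 18, 4 and 6 in cord at 4 and 7 weeks, 7 in cortex at 7 weeks and 11 in runs 88 to 90, 17 in spleen at 7 weeks, and 2, 26 and 6 in liver at 4 weeks, at 7 weeks and without animal 6. With a week 3 list at 10 points, 90.9% of sites kept direction in week 3 cord, but the call was lost (exact permutation p = 0.0563, adjusted p = 0.197). With that list 23.8% pointed toward neonatal ganglion and 1 reference passed. The share toward cord was 39.9% with the list of the replicate block (49.3% in matched lists), and toward spleen 82.1% with the authors' adjustment (68.9%). By sign flips over pairs 0 comparisons passed, with the direction kept at 100% of sites at day 3, 95.1% in ganglia of diet animals and 92.7% in cord of either set. Leaving out 1 library or animal gave 48 to 296 sites in ganglia of diet animals, 1 to 17 for control siRNA, 3 to 18 for Gadd45a, 0 to 19 for RG108, 5 to 17 for decitabine, 0 to 14 and 0 to 4 for paclitaxel in ganglion and cord, 0 to 1593 fetal, 0 to 201 neonatal, 464 to 1489 for ganglion against cord, 0 to 61 for ligation by diet, and for diet 0 to 51 in ganglion, 6 to 12 in cord, 1 to 33 in cortex, 1 to 7 in spleen and 1 to 9 in liver. No value could be had for paclitaxel in cord without control 3 or for neonatal ganglia without neonatal 2. Gene lists, with either distance to a gene's start, were not run. Fits that leave 1 library in a group assume that it varies like the others.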

Other observations

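The test of purified neurons was chosen after its result was seen; the tests of animal-variable sites, of the 2 methyltransferase inhibitors and of Gadd45a were chosen before, and the sites named here were chosen after their values were seen.

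Some sites were called again and again between different animals. Of 201 sites called in 10 such comparisons, 10 were called in 3 or more; chromosome 2 position 204484225 was called in 6 of them, of which 4 (cortex and the diet effects in ganglion, cord and spleen) use the same numbered rats, and its methylation ranged from 15.7% to 82.0% between spleens and from 6.0% to 80.3% between cortices of the animals compared. Sites called for RG108, decitabine, paclitaxel or Gadd45a siRNA had a median correlation of 0.32 over 8 animals between other tissues of the same animal, above matched lists (upper bound 0.08; permutation p = 0.0002, the smallest these lists allow). For sites of week 3 ligation, where ligated and sham libraries carry the same numbers, the median correlation was 0.01 (permutation p = 0.312). Part of the sites called between groups of different animals may therefore differ from animal to animal in every tissue, whatever the treatment. Inheritance of such differences was not tested.

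RG108 and decitabine both inhibit methyltransferases, so lower methylation was one hypothesis. As deposited, mean methylation was higher in both treated groups, by 0.27 points with RG108 and 0.79 points with decitabine (SD 0.42, n = 3; exact permutation p = 0.1, the smallest possible). With the authors' adjustment the differences were -0.05 and 0.36 points (SD 0.39 for decitabine), values within their spread. Neither treated group was lower as deposited, but with 3 and 3 libraries the exact permutation test cannot fall below p = 0.1. The hypothesis therefore stays undecided. The setting with the adjustment was chosen after the values were seen.

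If the ligation change lay in cells that purification removes, the spleen slope would be lower in purified neurons than in the input. It was 0.122 in neurons and 0.067 in the input, but with 1 sham library of each kind the comparison decides nothing.

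If Gadd45a knockdown returned week 3 sites toward sham, their signed mean would be lower than with control siRNA. It was higher by 0.98 points with an SD of 1.26, which leaves the hypothesis undecided.

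Methylation profiles also told animals apart: in 142 of 172 comparisons of a library with another tissue, the best match carried the same animal number. The ganglia numbered 16 and 18 matched each other's other tissues; without these animals the count was 121 of 132.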
